A study of Homo sapiens with 3 samples.

How the data were processed

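The study profiled UM-UC-3 cells, an established human bladder (urothelial) carcinoma line, by chromatin immunoprecipitation and sequencing (ChIP-seq) with an antibody against histone H2A acetylated at lysine 130. There were 3 libraries: 1 from cells exposed to cigarette smoke media, 1 from air-exposed cells and 1 input. Groups were taken from the treatment label of each sample. The treatment text (10% smoke media for 3 days) stands on all 3 samples, the air sample included, so the smoke group rests on the treatment label alone. No file of the input was used here, and it entered no comparison.

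Each immunoprecipitated library came with 1 peak list in the 10-column narrowPeak layout, called per library. Per the submitters' processing notes, Bowtie2, MACS and MACS2 were used and hg38 and mm10 were named as builds; their versions, settings and roles are not given in the sources used here. The peaks ran to the ends of the human chromosomes as the GRCh38.p14 gene table places them, so hg38 coordinates were used. The deposited score was a whole number of about 10 times the peak's −log10 p. The deposited fold of each peak is the authors' enrichment value. It was matched by fragments plus 1 over background plus 1, so it is lower than the plain ratio to background. The deposited −log10 p and −log10 q are those of the authors' peak caller. A final column held the deposited summit position. These values were used only to describe, rank or filter peaks within a list. Peak numbers in the names ran to 134206 in the smoke list and 230215 in the air list, far above the 23975 and 27010 peaks listed, and 63 and 56 of the first 100 numbers were kept. Both lists therefore hold a selection of the numbered peaks, by a filter not given in the sources used here. Both list names carry the same control code, which the labels do not explain.

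Read depth per library is unknown, since peak lists carry no totals. Intervals on shares are 95% Wilson intervals and cover counting error only. With 1 library per group no difference has a replicate check, and no p-value was computed. No leave-one-out or paired fit exists for this design. No rows overlapped within a list, so merging changed nothing, and neither list had a peak on chromosome Y.

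Peaks were called shared when they overlapped by at least 1 bp (bedtools 2.31.1). The expected overlap is the median of 100 random placements of the peaks of 1 list within their chromosomes. A local shift of each peak by 10 kb to 1 Mb was added after the data were examined, since whole-chromosome placement ignores assembly gaps and regional density. A shift of 2 to 5 kb was added later still for the overlap. Ranges beside medians are the lowest and highest of the 100. Genes came from the GRCh38.p14 gene table, 59098 genes of which 19974 are protein-coding, as gene spans with no strand or exons. Promoters were therefore replaced by the 1 kb around either gene end, and exon, intron and UTR classes by inside or outside a gene span. A peak was placed by its summit for location and by overlap for gene counts. Base composition under peaks had been planned and was left out, since no genome sequence was used here.

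Before the data were examined, 18 gene lists with 450 distinct genes were fixed from textbook knowledge; all genes matched, 1 of them by a synonym. They cover fatty acid synthesis, fatty acid oxidation, lipid uptake and storage, cholesterol synthesis, aryl hydrocarbon receptor and xenobiotic response, NRF2 antioxidant response, DNA damage response, inflammation, epithelial-mesenchymal transition, luminal and basal urothelial markers, glycolysis, cell cycle, histone acetylation enzymes and readers, histone H2A genes, and markers of neurons, hepatocytes and blood cells. Each list was set against 10000 random lists of protein-coding genes matched on gene-length decile. Percentiles describe these 2 libraries and are no test of the treatment. Random lists were not matched on gene density.

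Genes were named by a rule fixed in advance: FASN; list genes with a gene-end peak in 1 library and none of the other library within 1 kb of it, at most 3 per list and 12 per library by −log10 q; per library the 10 peaks of highest −log10 q with no peak of the other library within 1 kb; and the 5 shared peaks highest in both lists. Peaks outside protein-coding genes were named by the nearest gene end in place of the nearest start site. Other genes were named after their values were seen. Results of some single genes are not reported here.

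Alternatives covered the overlap definition, stricter thresholds (−log10 q of at least 5 and, added later, of at least 2; fold of at least 5), equal list sizes, gene-end distances of 500 bp and 3 kb, protein-coding genes alone, whole genes, unmatched random lists, ranking on fold, a 100 kb window at FASN, and leaving out chromosome X. The overlap was tested on simulated data for the smoke against air comparison, with 200 and then 1000 planted overlaps among 23975 peaks, and 200 and 1000 were recovered. The number of stacked fragments behind a peak was solved from its fold and p under a Poisson background, and in the same kind of test 19999 of 20000 simulated values were recovered. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 with seed 20240.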

Results

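Acetylation of histone H2A at lysine 130 was mapped by ChIP-seq in UM-UC-3 bladder carcinoma cells exposed to cigarette smoke media (10% for 3 days) or to air, with 1 library each and 1 input. The smoke list held 23975 peaks covering 6.07 Mb, with a median width of 225 bp. The air list held 27010 peaks covering 8.27 Mb, with a median width of 277 bp. Many peaks were weak by the authors' own values: 44.4% of smoke and 60.4% of air peaks had a q of 0.05 or lower. The median deposited fold, which adds 1 to fragments and to background, was 3.76 in smoke and 3.93 in air. The weakest listed q was 0.371 in smoke and 0.389 in air. Read depth is unknown, and with 1 library per group none of the differences below has a replicate check.

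FASN, the enzyme that builds palmitate from acetyl-CoA and malonyl-CoA and the gene the series title names, had no peak in either deposited list. Its gene lies on chromosome 17 from 82078338 to 82098236 (hg38), and neither list had a peak within 50 kb or within 100 kb of it. The nearest smoke peak (82368782 to 82369068) was 270.5 kb away, and the nearest air peak (81723254 to 81723465) was 354.9 kb away. Of 19974 protein-coding genes, 27.7% had no peak of either library within 50 kb, 14.4% none within 100 kb and 3.17% none within 270.5 kb, the distance at FASN. On chromosome 17 these shares were 39.7%, 20.2% and 3.68% of 1169 genes. The lists hold only a selection of the called peaks, by a filter not given. A called peak near FASN could have been left out of them. Acetylation at FASN below the calling threshold was not measured here either.

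Most genes of fatty acid synthesis had no peak, 21 of the 30 in the list. None of the 30 had a peak within 1 kb of a gene end in either library, against a median of 2 in random lists matched on gene length (percentile 8.78). Counting peaks anywhere over the gene or within 1 kb of it, 6 genes had peaks in both libraries, 2 in smoke alone and 1 in air alone. ACACA, the acetyl-CoA carboxylase that makes malonyl-CoA, held 7 smoke and 5 air peaks. HSD17B12, a ketoacyl reductase of fatty acid elongation, held 5 of each, and ME1, the cytosolic malic enzyme that supplies NADPH, held 3 smoke and 5 air peaks. The elongase gene ELOVL6, the dehydratase gene HACD2 and the second carboxylase gene ACACB completed the 6. The elongase genes ELOVL7 and ELOVL2 had 1 and 2 peaks in smoke alone, and ELOVL4 had 4 in air alone. Neither library had a peak over ACLY, SCD or SREBF1. The 9 genes with a peak in either library compare with a median of 14 in random lists matched on gene length (percentile 0.735). It was the 1 list of 18 outside the central 95% by this measure, and chance would give 0.9. Within 3 kb of gene ends 4 genes had a peak, against a random median of 4 (percentile 44.2). Over whole genes the balance of smoke-only over air-only genes was at percentile 71.1. Genes of this paragraph other than FASN were named after their values were seen.

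Among the 33 genes of fatty acid oxidation, 4 had peaks over the gene in both libraries, 5 in smoke alone and 2 in air alone. Those in both included EHHADH, an enzyme of peroxisomal oxidation, and the coactivator gene PPARGC1A with 5 smoke and 8 air peaks. HADHB, HADH, ECI2, ACADS and MLYCD had peaks in smoke alone, and ACADM and ETFDH in air alone. The ACADM peak was the only one at a gene end. It lay on chromosome 1 from 75724478 to 75724926, across the end of ACADM at 75724709, with an air fold of 4.69. The gene encodes the medium-chain acyl-CoA dehydrogenase. In lipid uptake and storage (32 genes), PPARG, ACSL1, ACSL6, CD36 and LPIN2 had peaks in both libraries, 2 genes in smoke alone and 3 in air alone. PLIN3, which coats lipid droplets, had the list's only gene-end peak, in air. Of 26 cholesterol synthesis genes, SQLE had peaks in both, CYP51A1 and FDFT1 in smoke alone, and 4 genes, SREBF2 among them, in air alone, none of them at a gene end. The smoke-minus-air balance over whole genes stood at percentiles 88.2, 42.8 and 26.0 for these lists, all inside the central 95% of random lists. Genes other than ACADM and PLIN3 were again named after their values were seen.

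**Figure D1:**
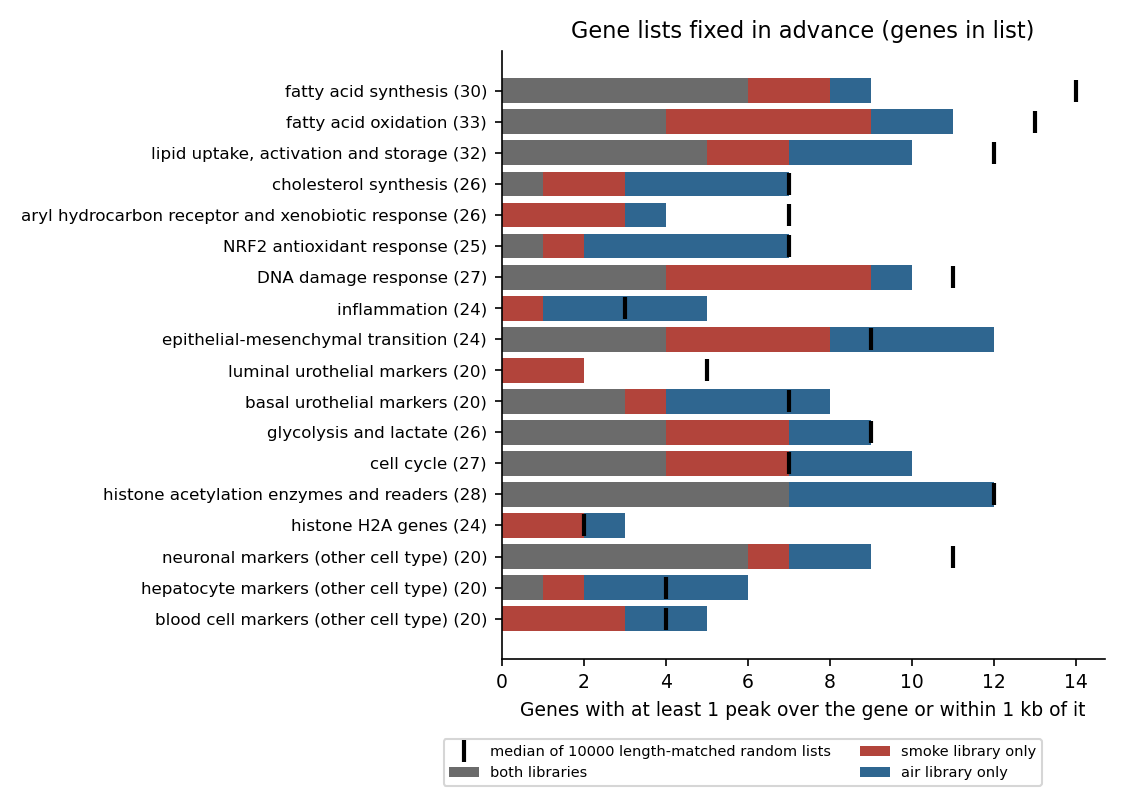
Number of genes per fixed list (horizontal axis) with at least 1 peak over the gene or within 1 kb of it, split into both libraries, smoke only and air only (1 library each), with the list size in brackets; black ticks mark the median of 10000 length-matched random lists. Fatty acid synthesis has 9 such genes against a random median of 14.

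DNA damage response and glycolysis were the lists with the most one-sided gene-end peaks. BRCA1, a gene of homologous recombination repair, had a smoke peak on chromosome 17 from 43170438 to 43170601, with its summit 164 bp outside the gene span (fold 4.26). Gene spans carried no strand or transcripts, so a peak at the end of a span need not lie at a promoter, here or at the genes below. MGMT, which removes alkyl groups from guanine, had a smoke peak on chromosome 10 at 129466331 to 129466556 (fold 3.82). MDM2, the ubiquitin ligase for p53, had one on chromosome 12 at 68807727 to 68807876 (fold 3.34). No DNA damage gene had a gene-end peak in air, and the balance stood at percentile 99.3. At a −log10 q of at least 2 it had 1 gene in smoke alone and stood at percentile 94.8, inside the central 95%. Over whole genes the list had 5 genes in smoke alone, 1 in air alone and 4 in both (percentile 95.2), back inside the central 95%. In glycolysis the 3 gene-end peaks were all in air: PFKM, the muscle phosphofructokinase (fold 5.16), PDHA1, a subunit of pyruvate dehydrogenase (fold 4.69), and HIF1A, the hypoxia-induced transcription factor (fold 3.65), at percentile 1.61. Over whole genes glycolysis had 3 genes in smoke alone, 2 in air alone and 4 in both, at percentile 73.3. For the smoke-minus-air balance, 0.9 of 18 lists would fall outside the central 95% by chance, against 2 at gene ends and 0 over whole genes.

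Of 26 genes of the aryl hydrocarbon receptor and xenobiotic response, AKR1C2, a ketosteroid reductase gene, and NAT2, an N-acetyltransferase gene for aromatic amines, had gene-end peaks in smoke alone (folds 5.37 and 4.30, percentile 97.0). Of textbook targets of the receptor, TIPARP had 1 peak, in air, UGT1A6 had 1, in smoke, and CYP1A1, CYP1B1 and AHRR had none in either library. Over whole genes 3 had peaks in smoke alone, 1 in air alone and 0 in both. In the NRF2 antioxidant list gene-end peaks lay in air alone at TXNRD1, a thioredoxin reductase gene, and SOD1, a superoxide dismutase gene (folds 3.82 and 3.48, percentile 5.81), and over whole genes 5 genes had peaks in air alone, 1 in smoke alone and 1 in both. Both lists were inside the central 95% of random lists. Inflammation genes had no gene-end peak; over whole genes NFKB1 had a peak in smoke alone and IL1B, IL6, TLR4 and STAT3 in air alone (percentile 4.93). Within 3 kb of gene ends the inflammation list had 4 genes in air alone and 0 in smoke alone, at percentile 0.955, outside the central 95%. These inflammation genes and the receptor targets were named after their values were seen.

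Of all 19974 protein-coding genes, 1020 had a gene-end peak in either library. Among basal urothelial markers, the keratin gene KRT6A had an air peak on chromosome 12 from 52487163 to 52487567 with a fold of 5.77 and a −log10 q of 3.82, the highest −log10 q among the named list genes. TP63 also had a gene-end peak in air alone. Over whole genes the basal list had 3 genes in both, 1 in smoke alone and 4 in air alone. Luminal markers had 2 genes in smoke alone, CYP2J2 and UPK1B, and 0 in air. In epithelial-mesenchymal transition CTNNB1, encoding beta-catenin (fold 4.06), and SNAI2 had gene-end peaks in air alone, and whole genes were split 4 in both, 4 in smoke alone and 4 in air alone. BUB1, a spindle checkpoint kinase gene, had the only gene-end peak of the cell cycle list, in air (fold 4.69), with whole genes split 4, 3 and 3 in the same order. TP63, SNAI2 and the luminal genes were named after their values were seen.

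Genes of histone acetylation and of H2A itself were also covered. SIRT1, a deacetylase gene, had a gene-end peak in air alone (fold 3.48), and over whole genes the list of 28 had 7 genes in both, 5 in air alone and 0 in smoke alone (percentile 4.23). H2AC15, a core H2A gene on chromosome 6, had a smoke peak from 27837799 to 27838005 (fold 4.15), the only gene-end peak of the H2A list, which over whole genes had 2 genes in smoke alone and 1 in air alone. Markers of other cell types had peaks too. Neuronal markers had 6 genes in both, 1 in smoke alone and 2 in air alone, hepatocyte markers 1, 1 and 4, and blood cell markers 0, 3 and 2. Gene-end peaks in this last list were at LYZ and CD79A in smoke (folds 3.76 and 2.92) and at CD14 in air (fold 3.90), and STMN2 had the neuronal one, in air. Among all fixed lists ATR, a DNA damage kinase gene, was the only gene that held a shared peak. STMN2 and ATR were named after their values were seen.

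The 10 strongest peaks of each library with no peak of the other within 1 kb lay inside protein-coding genes or up to 1505 kb from the nearest one. The strongest smoke peak, on chromosome 17 from 26881284 to 26881497, had a fold of 8.97 and a −log10 q of 65.8, and the nearest protein-coding gene, WSB1, was 413 kb away. It lay 114 kb from the end of a 4.11 Mb stretch with no peak in either list. The next were 264 kb from the cadherin gene CDH8 and 98.6 kb from DMRT2, each with a fold of 9.13 and a −log10 q of 9.74, and 109 kb from FAM86B2 (fold 7.33). Smoke peaks inside SLIT3, a ligand of axon guidance, AFF3 and DYNC2H1, a ciliary dynein heavy chain gene, had folds of 7.46, 7.65 and 7.52. The other 3 of the top 10 were nearest to LOC102723475, ALG10 and TRIQK. In air the strongest peak lay inside NPAS3, a transcription factor gene, on chromosome 14 from 33626382 to 33626844 with a fold of 8.70 and a −log10 q of 8.23. FOCAD and PAK5 also held top air peaks inside the gene (folds 8.12 and 7.19). A peak with its summit 6.15 kb from NR3C1, the glucocorticoid receptor gene, had a fold of 7.62. The other 6 were nearest to SLC15A1, RMP64, SLITRK1, OR6C74, IZUMO2 and SLC4A3.

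Few peaks were shared between smoke and air. Only 380 peaks of each list overlapped the other by at least 1 bp, 1.58% of smoke peaks (95% Wilson interval 1.43 to 1.75) and 1.41% of air peaks (1.27 to 1.55). Random placement gave a median of 127 for the smoke peaks (105 to 156 over 100 placements), local shifts of 10 kb to 1 Mb gave 153 (126 to 185), and shifts of 2 to 5 kb gave 187 (152 to 212). The 5 shared peaks ranking highest in both lists lay 671 kb from CXADR, 453 kb from ALG10B, 31.1 kb from GK5, 408 kb from ARRDC3 and inside ACSS3, which encodes a mitochondrial acyl-CoA synthetase for short chains. The ACSS3 pair lay on chromosome 12 at 81154650 to 81154880 in smoke (fold 4.84) and 81154487 to 81155014 in air (fold 5.80). Within 1 kb, 4.43% of smoke and 3.90% of air peaks had a neighbour in the other list. Random placement gave 2.40% and 2.13%, and local shifts gave 2.90% and 2.59%. At a −log10 q of at least 5 the lists had 18 and 26 peaks and shared 0, and random placement also gave 0. At a fold of at least 5 they shared 4. Random placement there gave a median of 1 for smoke peaks (0 to 3) and 0 for air peaks (0 to 4). Both list names carry the same control code, and a contribution of a shared control to the overlap was not separated.

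Peaks over the gene or within 1 kb of it were present at 4842 protein-coding genes in smoke and 5173 in air, with 2928 in both, 1914 in smoke alone and 2245 in air alone. Local shifts gave a median of 2815.5 genes in both (2749 to 2869), and independent lists of these sizes would give 1254. At gene ends 29 genes were in both, 420 in smoke alone and 571 in air alone.

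The share of peaks with a partner did not rise steadily with peak strength. Of the strongest 10% of smoke peaks 1.34% had an air partner (0.947 to 1.88), and of the weakest 10% 1.38% (0.982 to 1.93). In air both the strongest and the weakest 10% had a smoke partner in 1.70% of cases (1.28 to 2.26). Between them the share was uneven, from 0.740% (0.480 to 1.14) in part 5 of 10 to 1.78% (1.34 to 2.35) in part 6 of the air list. In smoke it ran from 1.34% to 1.83% by −log10 p. Ranked on fold, the smoke share ran more widely, from 1.001% (0.674 to 1.49) in part 4 to 2.25% (1.73 to 2.93) in part 5. The air share ranked on fold ran from 0.777% in part 5 to 1.85% in part 6. Many peaks had equal values, and ties were split between parts by the other value, then by chromosome and position. In smoke, parts 4, 5 and 6 by −log10 p all held peaks at 4.48. Swings between the middle parts therefore cannot be read as effects of strength alone.

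**Figure D2:**
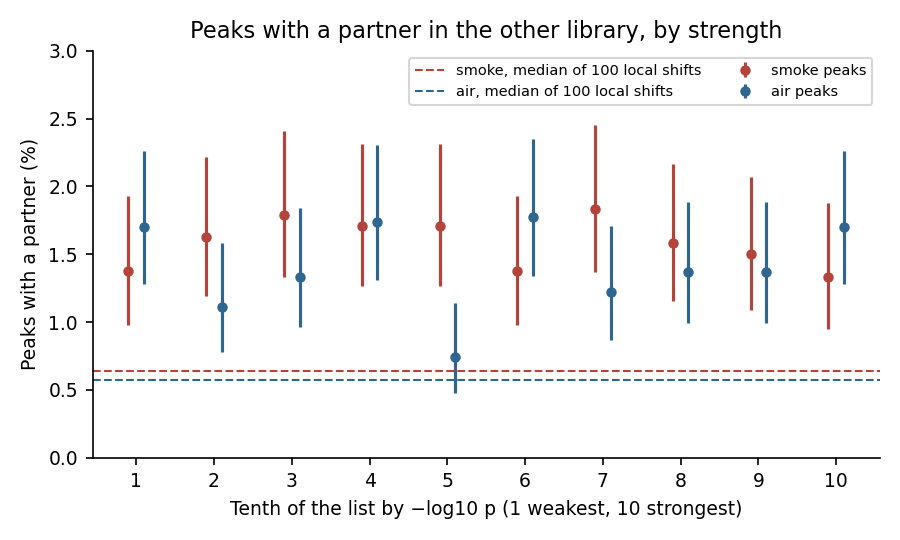
Percent of peaks with an overlapping peak in the other library (vertical axis) in 10 equal parts of each list ranked on −log10 p (horizontal axis, 10 strongest), 1 library per group; bars are 95% Wilson intervals and dashed lines the medians of 100 local shifts. The strongest part has 1.34% in smoke and 1.70% in air, no higher than the weakest part.

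Peaks of both lists lay at gene ends less often than randomly placed positions. Against local shifts only smoke peaks lay below the range, and this contrast between the libraries was not stable. At a −log10 q of at least 2, 5.43% of smoke summits lay near any gene end, inside the random range (5.14 to 7.17). In air 5.15% did, below the random range (5.46 to 6.88). Within 1 kb of an end of any annotated gene lay 5.01% of smoke summits (4.74 to 5.29) and 5.44% of air summits (5.17 to 5.72). Random placement gave 6.01% in both, with ranges of 5.65 to 6.49 for smoke and 5.72 to 6.31 for air. Local shifts gave 5.64% (5.23 to 5.97) and 5.62% (5.30 to 6.07). For protein-coding genes the shares were 1.58% in smoke and 1.87% in air, against 2.29% at random and 2.02% (1.83 to 2.27) and 2.04% (1.86 to 2.26) after local shifts. Inside gene spans lay 57.8% of smoke and 58.0% of air summits, against 55.7% and 55.6% at random and 56.8% (56.0 to 57.6) and 57.1% (56.4 to 57.9) after local shifts. Shared peaks lay inside genes less often, 49.5% (44.5 to 54.5), than unshared ones, 57.9% in smoke (57.3 to 58.5) and 58.1% in air (57.5 to 58.7).

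**Figure D3:**
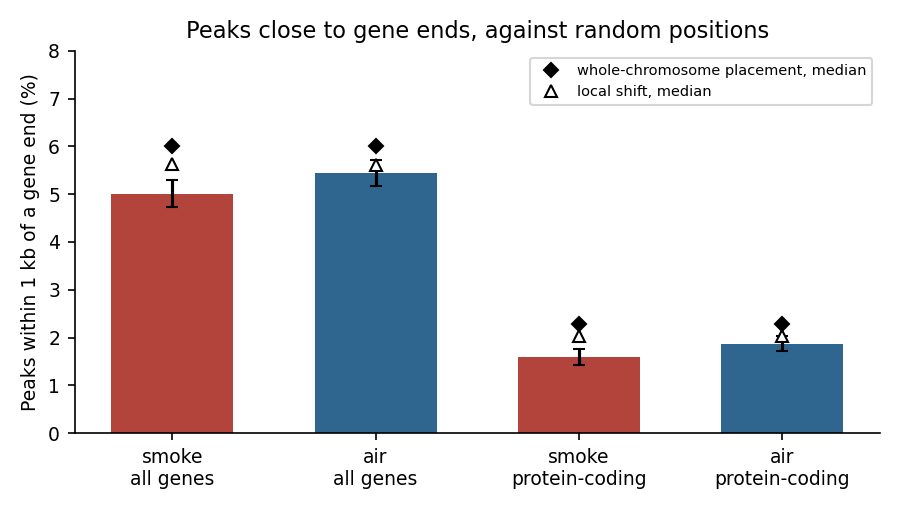
Percent of peak summits within 1 kb of a gene end (vertical axis) for all annotated genes and for protein-coding genes, 1 library per group; bars show the lists with 95% Wilson intervals, diamonds the median of random placements and triangles the median of local shifts. No bar rises above its diamond or triangle, with 5.01% against 6.01% in smoke for all genes.

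Smoke and air peaks were in a similar proportion on every chromosome. Density ran from 2.85 peaks per Mb on chromosome 22 to 10.7 on chromosome 12 in smoke, and from 3.44 to 12.4 on the same chromosomes in air. Smoke-only peaks made up 47.0% of all unshared peaks, and between 45.0% and 49.8% on single chromosomes. On 0 of 23 chromosomes did the 95% interval leave out the overall share.

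**Figure D4:**
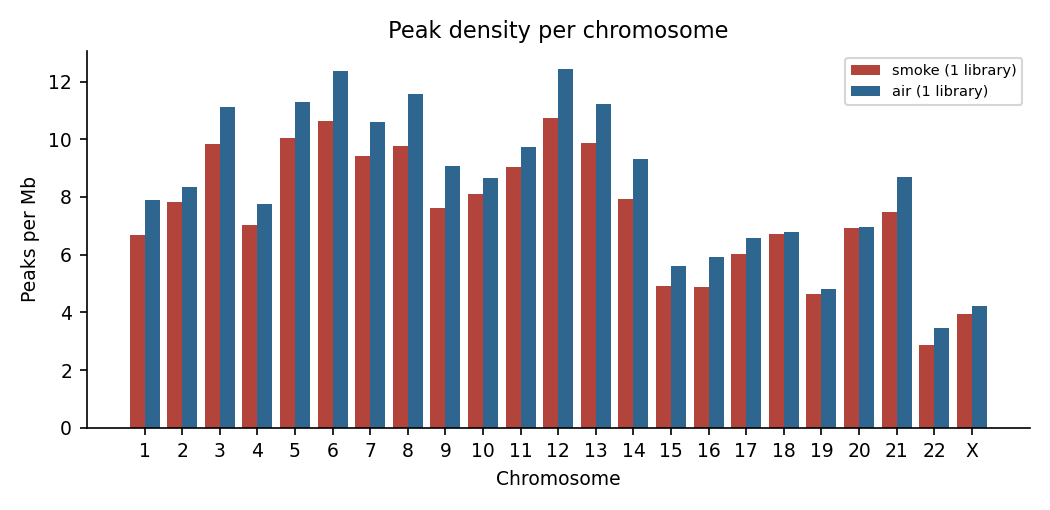
Peaks per Mb (vertical axis) on chromosomes 1 to 22 and X (horizontal axis) in the smoke and the air library, 1 bar per library. Both libraries are densest on chromosome 12 (10.7 and 12.4) and sparsest on chromosome 22 (2.85 and 3.44).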

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

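The threshold of −log10 q of at least 2 and the local shifts were chosen after the data were examined; the other alternatives were fixed before. The absence of listed peaks at FASN held in both libraries within 100 kb. A stricter threshold could not change it. The shares of peaks with a partner stayed inside their 95% intervals under several alternatives. These were equal list sizes, leaving out chromosome X, counting each row and the stronger part of 1 list. Ranking on fold kept the share inside its interval for the strongest 10% of each list, but not for every part. In smoke, part 4 of 10 had 1.71% ranked on −log10 p (1.26 to 2.31) and 1.001% ranked on fold. Ties at the borders of such middle parts were split by chromosome and position, so this difference is not one of ranking alone. Stricter thresholds left fewer peaks by construction: 18 smoke and 26 air peaks at a −log10 q of at least 5, 4144 and 6757 at 2, and 1373 and 2677 at a fold of at least 5. The shared part was then 0% in both at a −log10 q of 5, 0.386% and 0.237% at 2, and 0.291% and 0.149% at the fold threshold. Random placement fell too, to 0% in both at 5, 0.121% and 0.0740% at 2, and 0.0728% and 0% at the fold threshold. At 2 the ratio of the overlap to random placement was 3.2 in both lists. The 16 shared peaks there compare with at most 13 in smoke and 16 in air after local shifts. By overlap definition it was 0.526% of smoke and 0.466% of air peaks with reciprocal 50% overlap, 1.08% and 0.963% with summits within 200 bp, and 4.43% and 3.90% within 1 kb, where the strongest 10% of peaks had 3.84% and 4.48%. The ratio of the overlap to chance, 2.99 in smoke and 3.00 in air, was 2.48 and 2.47 against local shifts and 2.03 and 2.06 against shifts of 2 to 5 kb. For neighbours within 1 kb the ratio was lower, 1.84 and 1.83 against random placement and 1.53 and 1.51 against local shifts. The ratio of gene-end peaks to chance, 0.832 in smoke and 0.904 in air, was 0.880 in smoke within 3 kb. For protein-coding genes it was 0.691 and 0.816, at a −log10 q of at least 2 0.889 and 0.859, and against local shifts 0.888 and 0.968. At a −log10 q of 5 it was 1 in both, from 1 smoke and 2 air peaks. By their smoke-minus-air balance, 2 gene lists stood outside the central 95% at gene ends, 3 within 3 kb, 0 over whole genes, and 1, glycolysis, at a −log10 q of 2. At a −log10 q of 5 it was 0 by construction, since 0 protein-coding genes had a gene-end peak. Within 3 kb the 3 were DNA damage response, inflammation and epithelial-mesenchymal transition, and glycolysis was not among them. Fatty acid synthesis genes with gene-end peaks, 0 in each library, came to 3 in smoke alone and 1 in air alone within 3 kb, and to 2 and 1 over whole genes. The share of smoke-only peaks was 40.9% at a −log10 q of 5. Apart from the numbers of peaks and the random overlap at the same thresholds, the cause of these shifts was not tested. Base composition over whole peaks and at a stricter threshold was not run. Depth is unknown, so peaks missed for lack of reads could not be counted.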

Other observations

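Peak strength was a planned result, and its use as a test of missed thresholds was chosen after that result was seen, as were the tests of fragment numbers, local shifts and summit distances; those of raised background, whole-chromosome copy number and base composition were set before. The genes with the most peaks were very long ones in both libraries. CNTNAP2, a neurexin-family gene on chromosome 7 that spans 2.30 Mb, held 41 smoke and 53 air peaks, DLG2 held 42 and 44, and PTPRD held 47 and 36. GPC5, MACROD2 and CSMD3 followed, with 28 and 37, 32 and 28, and 28 and 29 peaks. Per Mb of gene, CNTNAP2 had 17.8 smoke peaks, against 10.7 on the densest chromosome. RBFOX1, the longest of them, had 17 smoke and 33 air peaks, or 6.87 smoke peaks per Mb, below that chromosome. In air RBFOX1 had 13.3 peaks per Mb, above the 12.4 of the densest chromosome. These genes were picked for their peak number.

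Peaks were concentrated in gene-poor parts of the genome. Among 2840 windows of 1 Mb, the 975 with at most 2 protein-coding genes held 10.1 ± 5.5 smoke and 11.1 ± 6.1 air peaks (mean ± SD over windows), and the 348 with at least 15 genes held 5.44 ± 3.63 and 5.78 ± 3.80. Copy number of whole chromosomes does not account for this: the median Spearman correlation of peaks with genes within chromosomes was −0.37 in smoke, and 20 of 23 chromosomes were negative. Base composition may do so, since over all windows the correlation was −0.31 in smoke and no genome sequence was used to part GC content from gene density. A true concentration of the mark in gene-poor chromatin stays open too, and no biological explanation was tested.

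Few peaks were shared between smoke and air. The 380 shared smoke peaks exceeded the highest of 100 local shifts by 195, and also the highest of 212 over shifts of 2 to 5 kb. For the air peaks the highest were 197 and 231, also below 380. Chance pile-ups spread as in these shifts do not reach 380. Shifted peaks could land where no peak can be called, so chance pile-ups confined to sequence where peaks can be called stay open. Peaks that just missed the threshold in the other library stay open. The strongest 10% of smoke peaks had a partner in 1.34% of cases, no more than the weakest 10%. In air both parts had a partner in 1.70% of cases. The strength scale between these parts ran only from a median of 5 to 9 fragments in smoke and 4 to 8 in air. A bar of at least 2 times the fragments was set for this test. The air medians just reached it and the smoke medians did not. The depth and the filter of the lists are also unknown. For the peaks with no partner, random pile-ups and a mark moved by smoke cannot be told apart: 97.7% of smoke peaks rested on at most 10 stacked fragments, and each group has 1 library.

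More peaks were shared than random placement gave, and regional density takes part of the excess and not all. Shifts of 10 kb to 1 Mb reached at most 185 shared smoke peaks and 197 shared air peaks, against 380. Shifts of 2 to 5 kb reached at most 212 and 231. Each peak was shifted on its own, so clustering of both libraries below 2 kb was not kept and stays open. Summit pairs also exceeded the longer shifts 1.76 times at 200 to 500 bp and 1.22 times at 500 to 1000 bp. The excess was 1.19 times at 1 to 5 kb and 1.08 times at 5 to 20 kb. A raised background was no more frequent among shared smoke peaks, 25.8%, than among unshared ones, 32.3% (31.7 to 32.9). This cannot exclude places where input is also high. The background was solved only from peaks already called against it, and no input file was used. Summit pairs within 200 bp exceeded local shifts 2.36 times, but 255 of the 260 smoke peaks in such pairs are shared peaks, so this restates the excess and bears on no cause of it. The same places carrying the mark in both libraries, places of high input and a control shared by both lists stay open. So do chance pile-ups confined to sequence where peaks can be called.

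A further hypothesis was that the authors' values rest on a small whole number of fragments per peak. Taking the fold as fragments plus 1 over background plus 1, and p from a Poisson model, a whole number matched both values for 100% of smoke peaks within a tolerance of 0.001, against 10.0% after p was shuffled between peaks. The median was 6 fragments in both lists, with a range of 4 to 119 in smoke and 3 to 15 in air. The top smoke peak on chromosome 17 was the one with 119 fragments, over a background of 12.4. It lay 114 kb from the end of a stretch of 4.11 Mb with no peak in either list.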
